A study of Drosophila melanogaster with 2 samples.

How the data were processed

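The data were peak lists from ChIP-seq of an eGFP-tagged Fer1 in whole Drosophila melanogaster embryos aged 6 to 24 h, with 2 biological replicates. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp and precipitated with an antibody against GFP. The labels also name a control library, which was not analysed here. For each of the builds dm6 and dm3, the authors deposited a list for each replicate, a list for the pooled replicates (both described in the labels as input for IDR) and a list past their IDR threshold. Each replicate and pooled list holds 30000 peaks. The aligner, the peak caller, the IDR threshold and the read filters are not given in the sources used here. Each peak has a signal value in the authors' units, a −log10 q value and a summit position, as deposited. The −log10 q values reach a shared maximum in each list, at which 32.7% of the dm6 pooled peaks lie, so the signal value was used to rank peaks. On dm6 the 7329 thresholded peaks are the same intervals as the 7329 pooled peaks with the highest signal. The threshold therefore acts as a limit on the pooled signal, and a thresholded peak need not be as strong in each replicate. Some peaks share an interval and differ in summit, and the thresholded list has 7169 distinct intervals. Signal values of replicate 1 were 1.48 times those of replicate 2 in the median of matched peaks, which can follow from depth or scaling, so signal values were compared within a list only. No read totals were at hand, so depth is unknown and intervals cover counting error over peaks or genes only.

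Coordinates are dm6 and 1-based. Sequence came from the Release 6 assembly of the genome, the same assembly as dm6, and genes came from Ensembl release 115. All peaks lay within the lengths of chromosomes 2L, 2R, 3L, 3R, 4 and X. The annotation gave 23998 transcription start sites, 19607 of them of protein-coding genes, with transposable elements left out. Positions on dm3 were used only within dm3. The analysis ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9, on single threads with seed 1.

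Replicates were compared by the overlap of their 7329 highest peaks, with at least 50% of both intervals shared, against 1000 circular shifts per chromosome. Summits within 1 kb of a TSS were counted against 1000 sets of random positions without N bases, with the same number per chromosome. Signal near and far from TSSs was compared with 100000 permutations. For 22 gene lists, the share of members with a summit within 1 kb of a TSS was set against all other protein-coding genes by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. Of the listed symbols, 7 were not found as written, of which 4 matched a single gene through synonyms. The others, dys (bHLH list), Dl (Notch list) and nos (segmentation list), each matched several genes and were left out. Members of a list are neither independent of each other nor samples. E-boxes and all strand-symmetric hexamers were compared between the sequence within 50 bp of each summit and a window of equal width centred 400 bp away on a randomly drawn side, by exact McNemar tests. Adjustment was over the 10 E-box forms and over all hexamers. The density on X was set against the other major arms by an exact binomial test on length without N bases. Named genes were fixed by rule: Fer1, the genes nearest to the 25 strongest peaks, up to 4 members of each list by signal (12 for lists past an adjusted p of 0.05), the 10 genes with most summits, and 5 hexamers in each direction. 1 gene that this rule selects is not reported here. The samples, tests, gene lists, named genes and most alternatives were fixed before the data were examined. With 1 group and no control library among the samples, no contrast between conditions was possible. P-values treat peaks or genes as units and do not measure variation between embryo collections.

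The alternatives were other overlap rules and list lengths, the highest 3664 peaks, windows of 500 bp and 5 kb, TSSs of coding genes only, gene lists matched on TSS number and gene length, sequence windows of 25 and 100 bp on each side, a control 1 kb away, the dm3 lists, and each replicate's own 7329 highest peaks in place of the thresholded list. In the last case "without replicate 1" stands for the list of replicate 2 alone, and the reverse.

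The code was tested on simulated data. With 60.3% of 7329 simulated intervals kept and moved by up to 50 bp, the overlap came out at 61.2%. Of 20 hexamers planted in 10% of summit windows, 20 were called, as were 20 of 20 at 5% and 19 of 20 at 2%, and 0 of all hexamers were called with nothing planted. The simulated summits were random positions, whereas real summit windows held 36.9% G or C against 43.0% in control windows. The simulation therefore does not show how often hexamers are called through such a difference in base content. A list of 40 genes with a peak at 66.7% of members was called in 90.5% of 200 draws, and unrelated lists in 0.310%. Random positions passed the TSS test in 1 of 20 runs.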

Results

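The series measured where the transcription factor Fer1 was enriched on chromatin in whole Drosophila melanogaster embryos of mixed sex, 6 to 24 h old. Fer1 is a basic helix-loop-helix (bHLH) protein related to mammalian PTF1A. bHLH proteins bind DNA as dimers at the E-box, a 6 bp site written CANNTG. Flies carried a transgene that fused eGFP to Fer1, and the fusion was recovered with an antibody against GFP (chromatin immunoprecipitation followed by sequencing, ChIP-seq). All samples formed 1 group of 2 biological replicates from separate embryo collections, so the comparisons below are between replicates, between parts of the genome and between groups of genes. On the dm6 build, the authors' list of peaks past their reproducibility threshold (the irreproducible discovery rate, IDR) held 7329 peaks, called the thresholded list here. Read totals are not part of peak lists, so the sequencing depth of each library is unknown. The signal value given for a peak is the authors' own and is used only within a list.

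Most of the strong peaks were shared by both replicates. The thresholded peaks had a median width of 360 bp (range 106 to 1946) and signal values from 110.1 to 4431, with a median of 182.1. Of the 7329 highest peaks of replicate 1, 65.4% (4791; 95% Clopper-Pearson interval 64.3 to 66.5) overlapped one of the 7329 highest of replicate 2 over at least 50% of both intervals. Circular shifts of replicate 2 along each chromosome gave 1.39% on average and 1.90% at most, and the one-sided permutation p was 0.001, the smallest that 1000 shifts can give. Across the 5162 thresholded peaks matched in both replicates, signal values correlated with a Spearman's rho of 0.808 and a Pearson's r of 0.877 on the log10 scale. This correlation is across peaks, which are not independent replicates. Of the 7329 thresholded peaks, 3963 (54.1%) overlapped one of the 7329 highest peaks of both replicates over 50% of both intervals, and 5947 (81.1%) did so when 1 bp of overlap was enough.

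**Figure D1:**
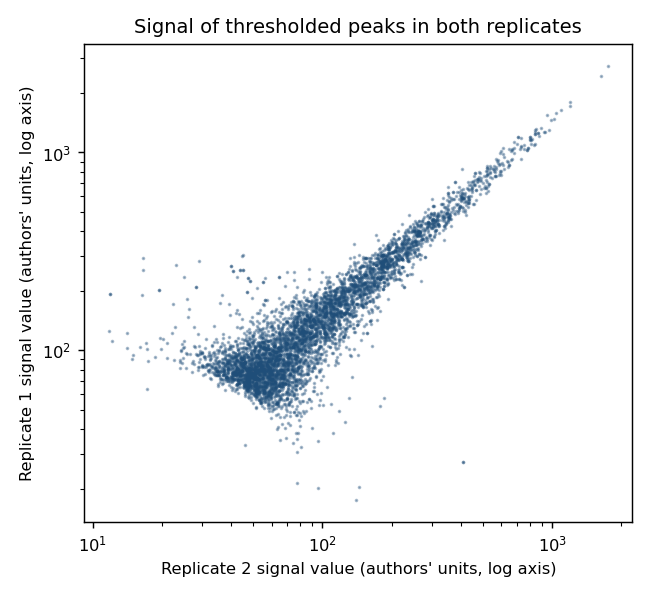
Signal value of each matched thresholded peak in replicate 1 (vertical log axis) against replicate 2 (horizontal log axis), in the authors' units. Each of the 5162 points is a peak, and the signal values rise together with a Spearman's rho of 0.808.

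The Fer1 gene itself carried peaks. Fer1 (FBgn0037475) lies on the plus strand of chromosome 3R from 7136206 to 7141972 (dm6), and 3 thresholded summits lay within 5 kb of it. The highest, at position 7139397 in an intron of Fer1, had a signal value of 599.9 and ranked 491 of 7329. The corresponding peak ranked 471 in replicate 1 and 527 in replicate 2. A further summit in the same intron, at 7139596, had a signal value of 312.7 (rank 1541). The remaining summit, at 7144712, had a signal value of 563.3 and lay 12 bp from the transcription start site (TSS) of the neighbouring gene CG2656. The sequence within 50 bp of the highest intronic summit, from 7139347 to 7139447, read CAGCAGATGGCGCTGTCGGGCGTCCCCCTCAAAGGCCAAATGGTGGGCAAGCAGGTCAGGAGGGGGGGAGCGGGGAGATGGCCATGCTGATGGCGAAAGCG and held 2 E-boxes, CAGATG starting at 7139350 and CAAATG at 7139383. The transgene carries Fer1 sequence whose extent is not given in the sources used here, so enrichment at this locus is not a test of the labels.

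**Figure D2:**
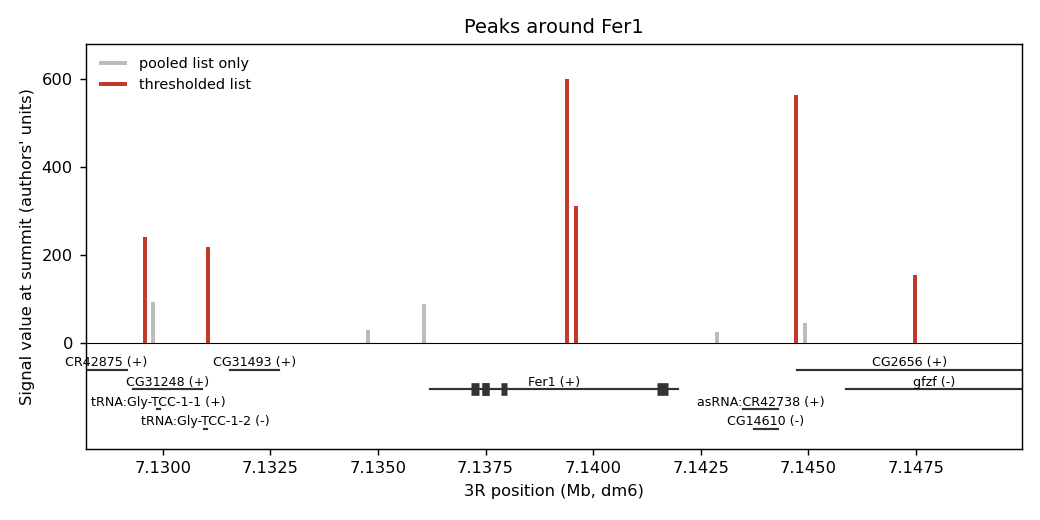
Signal value (authors' units) at each summit, against position on 3R (dm6), from 8 kb before to 8 kb past Fer1, with red lines for the thresholded list and grey lines for further peaks of the pooled list. Gene spans are drawn below with strand, thick boxes are Fer1 coding exons, and the highest line, at 599.9, falls in a Fer1 intron.

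Most of the strongest peaks lay close to TSSs. Of the 25 peaks with the highest signal, 19 had a summit within 1 kb of a protein-coding TSS, and 15 lay within 200 bp. The highest of all, with a signal value of 4431, was 24.3 times the list's median. Its summit, at 2L position 6612711, lay in an intron 1024 bp from the TSS of CG11050 (FBgn0031836), and it ranked 1 in both replicates. Next came a summit 1369 bp upstream of the TSS of cbt, a zinc finger transcription factor (signal 4345). That summit, at 2L position 481057, lay in an intron and within the span of the gene ush (476220 to 540560). A summit 34 bp upstream of Ugalt, a UDP-galactose transporter, followed (4045). Trl, which encodes the GAGA factor, had an intronic summit 1526 bp from its TSS (2967), and ph-p, a Polycomb group gene, had a summit 441 bp upstream of its TSS (2096). Chro, which encodes a chromosomal protein, had one in its 5' UTR (1963). Gapdh2, a glycolytic enzyme gene, had a summit 159 bp upstream (2622), and Hsp83, the Hsp90 chaperone gene, had one 105 bp from its TSS (2192). A summit 219 bp upstream of amon, a prohormone convertase, had a signal value of 2188, and one 158 bp upstream of Pal1, a peptide-amidating lyase, had 1969. The others were nearest to CG14100, CG4004, CG32772, px, Lk6, mRpL41, CG18549, PNPase, Tlk, CG13390, CG11309, Tina-1, Fkbp14, CG9663 and CG31145. None of the 25 ranked below 28 in replicate 1 or below 29 in replicate 2.

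Peaks clustered at transcription start sites. Of the 7329 summits, 4556 (62.2%) lay within 1 kb of an annotated TSS, 2.62 times the 23.7% of random positions (SD 0.498 over 1000 sets). The two-sided permutation p was 0.002, the smallest that 1000 sets can give. Within 200 bp the share was 41.2% against 6.18%, or 6.67 times. Around protein-coding TSSs, the median summit lay 54.5 bp upstream (quartiles 174 bp upstream and 45 bp downstream), and 64.1% of the 4314 summits within 1 kb were upstream. By annotation, 16.6% of summits fell in 5' UTRs against 3.37% of random positions, and 0.873% fell in coding exons against 16.8%. Introns held 47.0% of summits against 42.6%, and intergenic sequence held 31.5% against 30.6%. The median signal value was 185.4 within 1 kb of a TSS and 179.0 farther away, a difference of 6.44 (two-sided permutation p = 0.0155 across peaks, which are not replicates). With a window of 500 bp that difference was 3.44 and no longer passed (permutation p = 0.205). It was 10.8 with a window of 5 kb (permutation p = 0.00736), and 3.29 without replicate 1 (permutation p = 0.00248), on the lower signal scale of replicate 2's own list.

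**Figure D3:**
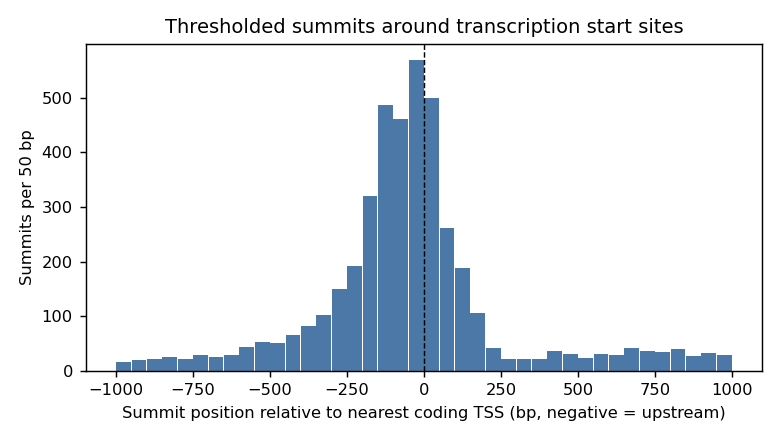
Number of thresholded summits per 50 bp (vertical axis, from 0) against the distance to the nearest protein-coding TSS (horizontal axis, bp, negative upstream). The highest bar, with 570 summits, is the one that ends at the TSS from upstream, the bar just downstream of the TSS holds 499, and the median summit lay 54.5 bp upstream.

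Ribosomal protein genes had promoter peaks far more often than other genes, and genes of the secretory pathway did so too. Of 13945 protein-coding genes, 4615 (33.1%) had a thresholded summit within 1 kb of a TSS. Among genes for cytoplasmic ribosomal proteins, 79 of 92 had one (85.9%, 95% Clopper-Pearson interval 77.0 to 92.3), against 32.7% of the other genes (Fisher's exact test, two-sided, adjusted p = 2.26e-24 over 22 lists). Among the highest were those at RpL7 (signal 1387), RpS27 (1023), RpL41 (996.1) and RpL23A (992.9), followed by RpL14, RpL30, RpL24, RpL19, RpL13A, RpL34b and RpLP0. Of 40 genes of the core secretory pathway, 25 had a promoter peak (62.5%, interval 45.8 to 77.3; Fisher's exact test, adjusted p = 0.000828). They included TRAM, a translocation protein of the endoplasmic reticulum (signal 1100), the coatomer genes alphaCOP (515.7), deltaCOP (308.5) and epsilonCOP (278.0), the translocon-associated SsRbeta (464.6), and Sec24AB (454.1) and Sec13 (259.7) of the COPII coat. The signal recognition particle genes Srp72 (338.7) and Srp14 (306.2), the chaperone genes Cnx99A and Calr, and the signal peptidase gene Spase22-23 also had one.

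Genes for digestive enzymes and chemosensory receptors rarely had promoter peaks. Of 39 digestive enzyme genes, which include the Jonah proteases, trypsins, amylases and maltases, 0 had one (95% Clopper-Pearson interval 0 to 9.03%; Fisher's exact test, adjusted p = 2.25e-06). Among odorant receptors, gustatory receptors and odorant-binding proteins, 4 of 170 had one (2.35%; exact test, adjusted p = 5.39e-23), namely Gr32a, Or88a, Obp83g and Gr63a. Of 29 chorion, yolk and accessory gland genes, 1 had a peak, Acp63F (3.45%; exact test, adjusted p = 0.000942). Against random lists matched on TSS number and gene length, these 3 lists still passed, with smaller differences of -20.3, -23.4 and -17.0 percentage points in place of -33.2, -31.1 and -29.7. Each of 3 developmental lists was also below the other genes. Of 26 segmentation genes, 2 had a peak, hry (signal 242.4) and ptc (144.9), which gave an adjusted p of 0.0198 in Fisher's exact test. Proneural and neuroblast genes had 3 of 28, brat (1089), numb (780.1) and scrt (208.0; exact test, adjusted p = 0.0385). Mesoderm and muscle genes had 5 of 37 at the same adjusted p (exact test), with rols, mbc, Mef2, Tm1 and sns between 152.4 and 217.9. The calls for these 3 developmental lists were not stable. For mesoderm and muscle genes the call was lost in every alternative run with Fisher's exact test (adjusted p from 0.109 to 0.314, with 0.314 without replicate 1 and 0.160 without replicate 2). Their difference from other genes was -19.6 percentage points in the main test, -12.0 without replicate 1 and -14.0 without replicate 2. For segmentation genes the difference was -25.4 points in the main test, -22.1 without replicate 1 and -21.4 without replicate 2, with adjusted p-values of 0.0555 and 0.0561 in the latter 2, and the adjusted p ranged from 4.77e-06 to 0.168 in Fisher's exact test. For proneural genes it ranged from 0.000611 to 0.498 (exact test), and the call was lost with a 500 bp window and in the highest 3664 peaks. The proneural difference was -22.4 points in the main test and -18.5 with the 500 bp window. It was -8.39 in the highest 3664 peaks and -36.3 with a 5 kb window. Against random lists matched on TSS number and gene length, the adjusted permutation p was 0.011 for mesoderm and segmentation genes and 0.0165 for proneural genes.

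The other 14 lists did not pass in the main test. The bHLH family, to which Fer1 belongs, had 14 of 37 members with a promoter peak (37.8%, interval 22.5 to 55.2; Fisher's exact test, adjusted p = 0.721), with the highest at trh (952.3), SREBP (562.1), Max (364.7) and bigmax (315.5). Notch pathway genes had 10 of 26, with the highest at numb, gro (617.4), neur (491.5) and E(spl)m3-HLH (404.0). Developmental signalling genes had 18 of 35 (51.4%; exact test, adjusted p = 0.0719), with spi, aos, Stat92E and brk highest. They did pass without replicate 1 (26.4 percentage points above other genes; exact test, adjusted p = 0.00668) and without replicate 2 (24.4 points above; exact test, adjusted p = 0.0126), and the adjusted p was 0.691 against matched lists (permutation). Neuron differentiation genes had 8 of 21, among them elav, the pan-neuronal RNA-binding protein gene (1832), cpo (736.0), Syx1A and Fas2. Glial genes had 5 of 11, led by moody (1236) and Gs2 (692.9), with loco and pnt lower. Salivary gland genes had 5 of 14, with fkh, the fork head regulator, at 1345, followed by trh, pip and ps. The salivary gland share was 35.7% in the main test and without replicate 2, and 21.4% without replicate 1. Midgut regulators had 5 of 17 (fkh, bowl, GATAe and Ptx1 highest), and tracheal genes had 4 of 16 (trh, bnl, pio and verm). Peptidergic and enteroendocrine genes had 7 of 31, with amon, svr (711.3), Pal2 and sNPF highest. Cell cycle genes had 14 of 31, with Dp (858.2), dup, RnrS and CycE highest. Photoreceptor genes had 6 of 22, with rdgC, Rh5, rdgB and norpA highest. Epidermal genes had 3 of 23 (shn, at 1802, snsl and Ddc), hemocyte and fat body genes had 3 of 21 (Adh, PPO3 and ush), and Hox genes had 0 of 8 (exact test, adjusted p = 0.118, 95% Clopper-Pearson interval 0 to 36.9%). These last 3 lists were lower than random lists matched on TSS number and gene length, with adjusted permutation p-values of 0.0165, 0.0308 and 0.0293 in that order, and did not pass in the alternatives run with Fisher's exact test (adjusted p from 0.0764 to 0.860).

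**Figure D4:**
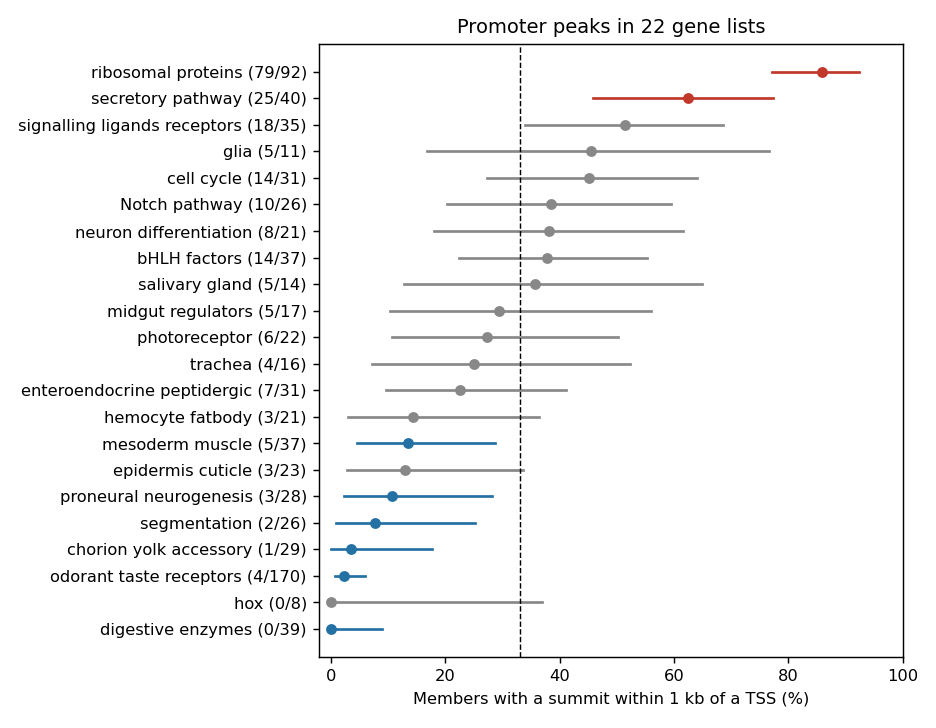
Share of the members of each of 22 gene lists with a thresholded summit within 1 kb of a TSS (horizontal axis, percent), with 95% Clopper-Pearson intervals as bars and the number of members beside each name. Red and blue mark lists above and below other genes past an adjusted p of 0.05 in Fisher's exact test, and the dashed line is the 33.1% of all protein-coding genes.

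The genes with most summits differed in length and in the density of their peaks. The gene with most summits, counted from 1 kb before to 1 kb past the gene, was shn, the zinc finger factor schnurri, with 21 over a gene of 58309 bp, or 3.48 per 10 kb against a genome value of 0.548. CG1677 and kirre, an immunoglobulin-family cell adhesion gene, each had 20, but per 10 kb CG1677 had 1.58, and kirre, a gene of 394149 bp, had 0.505, below the genome value. The others were sbb (19), Tlk (18), bun (18), Svil (16), CG32264 (15), Eip75B, an ecdysone-induced nuclear receptor (15), and mam, the Notch coactivator mastermind (15). Of the 13945 coding genes, 282 had 5 or more. In the highest 3664 peaks shn again led, with 12, while CG1677 led without replicate 1, with 20, and kirre without replicate 2, with 23. The count at a gene includes the peaks of any gene nested in it.

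E-boxes as a class were not more frequent at summits, and in the main test 1 form was. CANNTG occurred within 50 bp of 37.8% of the summits (2770 of 7329) and in 40.2% of equally wide windows 400 bp away (2944), which was lower at the summit (exact McNemar test, two-sided, p = 0.00336). The difference of -2.37 percentage points was -4.30 with the control 1 kb away and -4.97 in the highest 3664 peaks (exact tests, p = 1.02e-07 and 1.33e-05). Among the 10 forms, CAGCTG was higher at the summit, in 435 windows (5.94%) against 327 (4.46%; exact McNemar test, adjusted p = 0.000628). The excess of 1.47 percentage points was 0.873 without replicate 1 and 0.846 without replicate 2 (exact tests, adjusted p = 0.0289 and 0.0358). CAGCTG was not at its highest at the summit itself, since windows centred 150 bp to either side held it in 6.45% and 6.40%. CAACTG (386 against 497), CACCTG (209 against 285) and CAAGTG (400 against 476) were lower at the summit than 400 bp away, with adjusted p-values of 0.000628, 0.00171 and 0.0219 in the exact test. These calls were lost for CAACTG in the window of 25 bp to each side (exact test, adjusted p = 0.291) and for CACCTG in that window (0.0691) and over 1 kb from TSSs (0.341). For CAAGTG the call was lost with the control 1 kb away (exact test, adjusted p = 0.0721), over 1 kb from TSSs (0.341) and in the highest 3664 peaks (0.0518). The differences ranged over the alternatives from -2.92 to -0.382 percentage points for CAACTG, from -2.48 to -0.505 for CACCTG and from -1.58, without replicate 1, to -0.791 for CAAGTG. Over the alternatives the adjusted p ranged from 4.1e-05 to 0.291 for CAACTG, from 1.82e-08 to 0.341 for CACCTG and from 0.00091 to 0.341 for CAAGTG (exact tests). Base content differed too, with 36.9% G or C in summit windows against 43.0% in control windows. For hexamers with 3 G or C, the median log2 ratio of summit to control was -0.167 near TSSs and -0.296 over 1 kb away. It was -0.354 and -0.691 with 4 G or C, and 0.0882 and 0.246 with 2, as in CATATG. Whether E-boxes as a class or these forms differed by more than base content gives was not tested. CATATG, in 291 windows against 263, did not pass in the main test (exact McNemar, adjusted p = 0.348). It did pass, as higher at the summit, in every alternative (exact tests, adjusted p from 0.00737 to 0.0480) except the window of 25 bp to each side (136 against 131; exact test, adjusted p = 0.896). CAGATG, CACATG and CACGTG also did not pass in the main test (exact tests, adjusted p = 0.137, 0.0533 and 0.753). Each passed as lower at the summit in some alternatives. The smallest adjusted p was 7.08e-05 for CAGATG and 0.000701 for CACATG, both with the control 1 kb away, and 0.0204 for CACGTG without replicate 2 (exact tests). The share with CAGCTG fell with peak strength, from 7.23% (95% Clopper-Pearson interval 5.96 to 8.68) among the 1466 weakest peaks to 3.62% (2.72 to 4.70) among the 1466 strongest. The Spearman's rho of presence with signal was -0.0637 (two-sided permutation p = 1e-05, the smallest 100000 permutations can give). It was -0.0371 without replicate 1 (permutation p = 0.00147) and -0.0422 in the window of 25 bp to each side (permutation p = 0.00036). The excess of CAGCTG was lost in the highest 3664 peaks (-0.0546 percentage points, exact test, adjusted p = 0.955). At the 2773 peaks over 1 kb from a TSS, 117 summit windows had CAGCTG against 123 control windows when the side of each control window was drawn anew (-0.216 points, exact test, adjusted p = 0.738), and against 103 with the sides of the main test, so the sign there depended on the control. With the control window 1 kb away the excess was 0.723 points and the adjusted p was 0.0853 (exact test). Adjusted p-values for CAGCTG ranged from 0.000363 to 0.955 over the alternatives (exact tests).

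Summits were rich in A and T. The windows within 50 bp of summits had 36.9% G or C on average, against 43.0% in the control windows. Among all strand-symmetric hexamers, 424 were more frequent at summits and 815 less frequent at an adjusted p under 0.05 (exact McNemar test). The 5 with the smallest p among the higher ones were AAATAT, found at 29.6% of summits against 16.5% of control windows, TAAATA (26.1% against 14.5%), AAAATA, AAATAA and TTAAAA. The 5 among the lower ones were CCAGGA (0.901% against 4.15%), CTCCTC (1.57% against 5.38%), AGGAGG, GGAGGA and CGAGGA. Of the 424 higher hexamers, 220 had at most 1 G or C, and 4 had 4 or more.

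**Figure D5:**
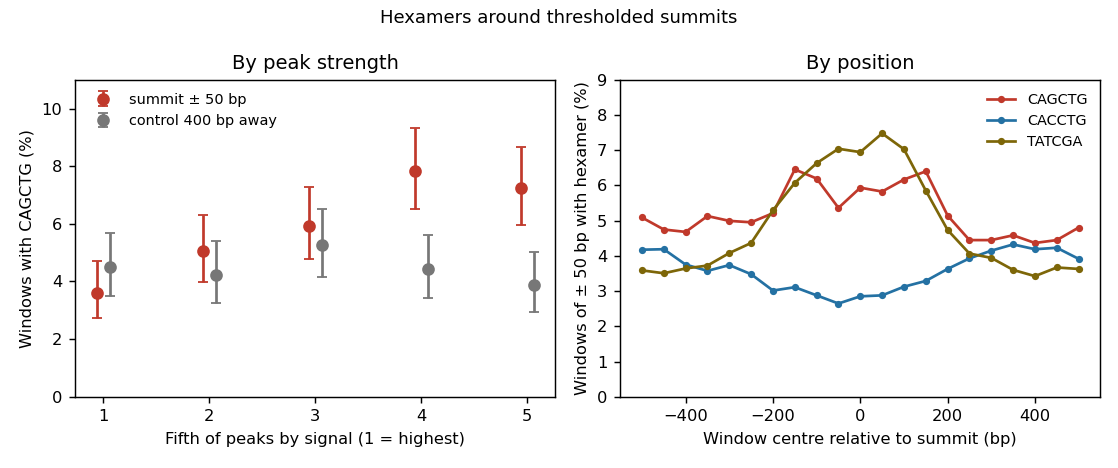
Left, percent of windows with CAGCTG within 50 bp of the summit (red) and 400 bp away (grey) in each of 5 equal classes of peaks by signal, with 95% Clopper-Pearson intervals, 3.62% at the summits of the strongest class and 7.23% at those of the weakest. Right, percent of windows reaching 50 bp to each side that held CAGCTG (red, 5.94% at the summit), CACCTG (blue, 2.85%) and TATCGA (brown, 6.95%) against the window's position relative to the summit (bp). CAGCTG was higher at -150 bp (6.45%) and 150 bp (6.40%) than at the summit.

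The density of peaks on the X chromosome was close to that on the autosomes. It held 1309 thresholded peaks, or 55.8 per Mb, against 55.0 per Mb on arms 2L, 2R, 3L and 3R together (ratio 1.01; exact binomial test, two-sided, p = 0.657). By arm, 2L had 56.9, 2R 56.5, 3L 55.3 and 3R 52.1 per Mb, and the small chromosome 4 had 25.5 per Mb (34 peaks). X had 93.5 coding genes per Mb, against 97.8 on 3L to 113.0 on 2L among the other major arms. In embryos of mixed sex, X also has fewer copies than the autosomes. The ratio was not adjusted for either difference. Among the peaks over 1 kb from a TSS, X had 24.9 per Mb against 20.03, a ratio of 1.24 (584 and 2180 peaks, exact binomial test, p = 5.12e-06). These densities are per Mb of all sequence, not of sequence over 1 kb from a TSS, whose share may differ between X and the other arms. The test also treats summits as independent, although some lie in clusters.

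The authors' thresholded lists for the older dm3 build and for dm6 were close in length and median signal, and the pooled lists differed more. The thresholded dm3 list held 7171 peaks against 7329 on dm6, with a median signal value of 181.7 against 182.1 (ratio 0.998). In the pooled lists the median signal value was 52.6 on dm3 against 55.4 on dm6, and 41.0% of dm3 peaks against 32.7% of dm6 peaks had the highest q value of their list. Of these, 5133 on dm3 and 2482 on dm6 lay outside the thresholded list. No coordinates were converted between builds, and the lists were not matched peak by peak.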

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

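The following values come from peaks outside the thresholded list. On dm3, 14 peaks of the pooled list lay on unplaced or heterochromatic sequence, and 0 of them reached the thresholded list. On dm6, 2482 pooled peaks had the highest −log10 q value in the list and were still outside the thresholded list, so the q value alone does not separate them from thresholded peaks.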

How the results depend on the processing

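Of 58 values of the main results under the alternatives, 48 kept their direction and side of the threshold or stayed within the set bounds. For counts, only the size of the count was judged, so the lists or genes behind a kept count can differ. The use of summits within 100 bp for the correlation and of the opposite side for the sequence control were chosen after seeing the data. Requiring both replicates over 50% of intervals left 3963 peaks, since the rule is stricter. Spearman's rho between replicates was 0.824 with 1 bp of overlap, 0.870 in the highest 3664 peaks and 0.797 with summits within 100 bp. The number of gene lists past the threshold was 5 in place of 8 with a 500 bp window and 5 in the highest 3664 peaks, which leave fewer genes with a peak. The signal difference near TSSs was 3.44 with a 500 bp window, and the cause was not tested. The gene with most summits had 12 in the highest 3664 peaks, which hold fewer summits. The density ratio of X to autosomes, per Mb of all sequence, was 0.958 in the highest 3664 peaks and 1.24 over 1 kb from TSSs. The cause was not tested. The excess of CAGCTG was -0.0546 percentage points in the highest 3664 peaks, and the cause was not tested. Over 1 kb from TSSs it was -0.216 (117 windows against 123) with control sides drawn anew, and 117 against 103 with the sides of the main test. Of 48 further values for single gene lists, 37 kept their call and 11 lost it, all 11 in the segmentation, proneural and mesoderm lists. Of 32 values for E-box forms, 23 kept their call, 7 lost it and 2 changed sign. From the replicates alone, the overlap with TSSs was 2.63 to 2.68 times random, the lists past the threshold numbered 7 in both (segmentation and mesoderm lost, developmental signalling gained), and the best rank near Fer1 was 471 to 504, where 504 is the summit near CG2656 and the intronic peak ranked 527. Against matched lists 11 passed. No paired analysis was possible because the samples form 1 group. Unknown depth limits what an absent peak means.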

Other observations

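The gene symbol families, the hexamers within base-content classes and the non-coding genes below were examined only after the main results were seen, as were 5 of the 8 tests of explanations; the tests of neighbouring genes, of tRNA genes and of the E-boxes in Fer1 were set out beforehand. Grouped by the leading letters of their symbols, 43 families had at least 15 coding genes. Above other genes in Fisher's exact test stood 34 of 38 RpS genes, 41 of 50 RpL genes, 25 of 47 genes of the large mitochondrial ribosomal subunit (mRpL; Fisher's exact test, adjusted p = 0.0129), 12 of 20 Atg autophagy genes and 12 of 20 Sec genes (both exact, adjusted p = 0.0336). Other families, such as mRpS (13 of 26) and eIF (21 of 44), did not pass (exact, adjusted p = 0.133 and 0.0839). Among those below other genes were 5 of 71 Cpr cuticle genes, 0 of 23 Twdl genes, 0 of 25 Osi genes, 8 of 85 Cyp genes, 1 of 60 Ir and 1 of 59 Or receptor genes. Symbols beginning with His, mostly the repeated histone genes, had 3 of 116 (exact test, adjusted p = 1.11e-14), and reads from near-identical copies cannot be assigned to one of them.

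Hexamers were ranked among others of equal G and C content, separately near and far from TSSs, and no test compared near with far. Near TSSs, TATCGA, part of the DNA replication-related element of Drosophila promoters, occurred at 413 of 4556 summits against 178 control windows (exact McNemar test, adjusted p = 3.54e-21). CGATAG, which overlaps it, was at 324 against 122, and ACACTG was at 386 against 193. Over 1 kb from TSSs, ATATTA was at 521 of 2773 summits against 193, and CTACAC at 112 against 52 (exact test, adjusted p = 2.08e-05). TTATAA was higher in both places, at 364 against 215 windows near and 297 against 133 far. Hexamers without G or C were higher in general, with a median log2 ratio of summit to control of 0.635 near and 0.757 far. That of TTATAA was 0.758 near and 1.16 far, and that of ATATTA was 1.43 far. Among non-coding genes, 79 of 290 tRNA genes (27.2%) and 73 of 269 snoRNA genes (27.1%) had a summit within 1 kb, against 9.38% of random positions, 5.97% of pseudogenes and 31.2% of protein-coding genes counted in the same way. Of 99 rRNA genes, 0 had one (95% Clopper-Pearson upper bound 3.66%), but reads from their repeated copies cannot be assigned to one of them. Many of these genes are clustered or lie within other genes, so they are not independent.

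The excess of CAGCTG at summits was set against 3 explanations. For base content, the ratio of CAGCTG between summit and control lay at percentile 99.6 of hexamers with 4 G or C. CAGCTG was picked for its excess in the same data, and only 4 of the 424 higher hexamers had 4 or more G or C. A high percentile therefore followed from that choice, and the test was set out after the results were seen. It cannot decide whether base content gave the excess. A site that sets the strength of Fer1 peaks would give a rise of CAGCTG with signal, whereas the share fell (rho = -0.0637, and -0.0371 without replicate 1). That fall was known when this explanation was set out, so it is not a separate test of it. A sequence of these promoters that is not placed at the summit remained a candidate explanation: 399 summits had CAGCTG at the summit and not 100 bp away, and 426 the reverse (exact McNemar p = 0.365, difference -0.368 points, 95% interval -1.14 to 0.40), and the excess was 1.56 points larger near TSSs than far from them (117 against 103 windows far) with the 400 bp control of the main test (permutation p = 0.0415). The comparison of near with far was also set out after the results were seen. It rests on the draw of control sides of the main test, and another draw gave 117 against 123 windows far. It is therefore weak evidence. A promoter sequence of this kind leaves open whether weak peaks with CAGCTG are bound by Fer1.

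Peaks at ribosomal protein genes were not accounted for by gene structure, since random lists matched on TSS number and gene length had peaks at 32.4% of members against 85.9%. Peaks of neighbouring genes were argued against, because in 96.2% of the ribosomal protein genes with a peak (76 of 79) the closest summit was nearest to the gene itself. Enrichment at strongly transcribed promoters whatever protein is tagged cannot be told apart from binding by Fer1. The 27.2% of tRNA genes with a summit goes with such enrichment and the 0 of 99 rRNA genes does not. Repeated copies leave the rRNA value undecided. Whether summits near tRNA genes belong to coding promoters close by was not tested, so the tRNA value is undecided too. Ribosomal promoter peaks had E-boxes as often as other promoter peaks within error (35.6%, 37 of 104, against 37.6%, Fisher's exact p = 0.759). The control library, which bears on this, was not analysed here.

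For the Fer1 intron, extra copies of the region carried by the transgene and binding by Fer1 to its own gene cannot be told apart. The 20 kb on either side of the Fer1 TSS held 23 pooled-list peaks against a median of 10 for coding genes on 3R, which is percentile 88.8, and the percentile was 88.7 in the list of replicate 1, 98.2 in that of replicate 2 and 94.9 in the thresholded list. The 2 E-boxes at the highest summit are more than in 91.5% of summit windows, short of the 95% set for an unusual cluster. The extent of the transgene is not given in the sources used here.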
